A study of Mus musculus with 46 samples.

How the data were processed

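The follicles were isolated from ovaries of CD-1 mice, encapsulated in alginate and cultured for 8 days, 1 to a well, per the labels, before hCG at 1.5 IU/ml was added with 10 ng/ml EGF and 10 mIU/ml recombinant follicle-stimulating hormone. Libraries were prepared from single follicles with Smart-Seq2, which amplifies polyadenylated RNA, and Nextera XT, and sequenced as paired ends. These libraries are not stranded, so reads of overlapping genes on opposite strands cannot be told apart. Per the submitters' processing notes, reads were aligned to GRCm38 with HISAT2 and compared with DESeq2 in Partek, with no versions given.

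Of the deposited files, the authors' count table holds whole numbers for 25147 genes, adjusted between the batches with ComBat-seq according to its own name, with settings not stated. A further deposited table holds TPM (transcript abundances scaled for gene length and library size) for 25122 genes, computed by the authors from the adjusted counts according to its name. The authors' deposited table of comparisons with 0 h holds 19925 genes with a p-value, a step-up false discovery rate and a signed fold change, per the file headers. Its remaining column, a summed signal named total counts, holds values that are not whole, so it was normalized by the authors before the file was deposited, and it was not used. Of the columns of the count table, and likewise of the TPM table, 10 matched no described sample and were not used. The 46 described follicles were grouped by hours after hCG and batch as labeled, and 5 of the 9 follicles at 0 h have descriptions ending in "_ds", whose meaning is not given. Gene symbols were matched to GENCODE M21 (GRCm38), in which 19557 of 25147 occurred once, and 25 names in the table had the form of dates and were not translated. The total count per library ranged from 241442 to 5185044.

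Counts were fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, filterByExpr on the time groups) with terms for time and batch, all 46 libraries and Benjamini-Hochberg adjustment over genes. A gene was called at an adjusted p under 0.05, and 8629 genes were tested, with a biological coefficient of variation of 34.0%. The tests covered 1 h, 4 h and 8 h against 0 h, 4 h against 1 h, 8 h against 4 h, all times together, and in the 26 follicles at 1 h and 4 h the difference of that step between the batches. In the tests against 0 h, the batch term lets 1 h and 4 h rest mainly on batch 2 and makes 8 h a sum of differences within batches. The SE of a fold change was its size divided by the square root of F, and log2 CPM were computed with a prior count of 2. Where a group had 0 counts in every library the fold was bounded by 3 counts over the group. With 1 to 3 counts the ratio of counts at equal depth was given with a 95% exact binomial interval. These bounds and ratios pooled the counts of all libraries of a group, with no batch term.

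Before the data were examined, 22 gene lists, the tests, most alternatives and the rule for named genes were fixed. The lists were immediate early genes, EGF ligands and ERK feedback, cumulus expansion matrix, the progesterone receptor network, prostaglandins, luteinization and progesterone synthesis, follicular phase granulosa genes, cholesterol synthesis, proteases and matrix remodeling, inflammation and cytokines, meiotic arrest signaling, the cell cycle, hypoxia with glycolysis and angiogenesis, heat shock, folding and amino acid stress, mitochondrially encoded genes, and markers of oocyte, theca and stroma, smooth muscle, endothelium, leukocytes and surface epithelium. Of these, 19 had at least 3 genes measured and were tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists of a comparison), and again with an estimated correlation. Named genes were the 10 largest rises and 10 largest falls in each comparison with 0 h and 5 and 5 in each step, among called genes with a mean log2 CPM of at least 3 and a gene name that is not a provisional identifier. They also needed the same sign in batch 2 alone (1 h and 4 h), without the batch term (8 h) or in batch 1 alone (steps). The rule added up to 2 called rises and 2 called falls of each list, and 24 genes of ovulation always, whatever their result.

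Alternatives were RLE factors, no filter on low counts, no batch term, a term for the 3 library sets (plate 1, plate 2 and the set of batch 2), a block for the replicate number, either batch alone, no "_ds" libraries, DESeq2 1.42.0, leaving out each of the 6 batch 2 libraries after hCG in the gene comparisons, and limma on log2 TPM with pseudocounts of 1 and 0.1 (mean TPM of at least 1). Others were chosen after the data were seen, namely the genes counted in batch 2 after hCG alone, all libraries thinned to 241442 counts, and leaving out 0 h replicates 1 and 3, 4 h replicate 10 and 8 h replicate 4. Leaving out the 6 libraries in the joint test of the times, in the difference between batches and in the list tests was added then too. On simulated data with known changes of 1.5-fold, 2-fold and 4-fold in these libraries, the comparisons with 0 h recovered 2.99% to 10.4%, 28.4% to 37.3% and 89.4% to 92.4% of changed genes. For the steps the shares were 25.4% to 32.8%, 65.7% to 74.2% and 98.5%, and 2.22% to 7.09% of calls were false. The difference between batches recovered 47.1% of 4-fold changes and 1.85% of 2-fold changes, so that smaller ones were mostly out of reach. No pair of libraries was a copy of another (lowest chi-square per degree of freedom 3.86). Batch adjustment was tested with ComBat-seq of sva 3.50.0 on the deposited counts, with chosen genes set to 0.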

Results

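The transcriptomes of 46 mouse ovarian follicles were measured, with each library made from the polyadenylated RNA of a single follicle of CD-1 mice, an outbred stock. Follicles grew for 8 days in alginate, a gel that keeps their shape, and then received human chorionic gonadotropin (hCG), which acts on the receptor for luteinizing hormone and triggers ovulation. Libraries were made at 0 h (9 follicles), 1 h (13), 4 h (13) and 8 h (11) after hCG, in 2 batches. Batch 1 held 10 follicles at 1 h, 10 at 4 h and all 11 at 8 h. Batch 2 held all 9 follicles at 0 h, 3 at 1 h and 3 at 4 h. The labels name no follicles kept without hCG for the same times, and the hCG medium also held serum, epidermal growth factor (EGF) and follicle-stimulating hormone, so each comparison is between times. They do not tie follicles to animals either, so p-values measure the spread between follicles.

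The total count per library ranged from 241442 to 5185044, with medians of 3286107 at 0 h, 730895 at 1 h, 1432395 at 4 h and 1755429 at 8 h. Between 8964 and 15051 genes had a count in each library. The share of counts in mitochondrial genes, taken without the set of 3332 genes described next, was 10.3% ± 1.25 (SD, n = 9) at 0 h and 11.8% ± 1.83 (SD, n = 13) at 1 h. It was 9.91% ± 1.67 (SD, n = 13) at 4 h and 9.78% ± 0.848 (SD, n = 11) at 8 h. From 1 h to 4 h it went from 12.4% ± 1.43 to 9.27% ± 1.09 in batch 1 (SD, n = 10 each) and from 9.68% ± 1.53 to 12.03% ± 1.65 in batch 2 (SD, n = 3 each). A set of 3332 genes had counts in batch 1 and 0 counts in all 6 batch 2 libraries made after hCG. These genes held 22.6% to 46.2% of the counts of each 0 h library and at most 0.0667% of those of any later library. Cxxc4 (ENSMUSG00000044365.15, chromosome 3 from 134236484 to 134262161, GRCm38) was among them, with a mean count of 54894 ± 33129 (SD, n = 9) at 0 h and of 1.03 in batch 1. All 20 of these genes that were tested were called lower at 1 h, 4 h and 8 h than at 0 h, by more than any other gene. Their values are kept apart below.

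**Figure D1:**
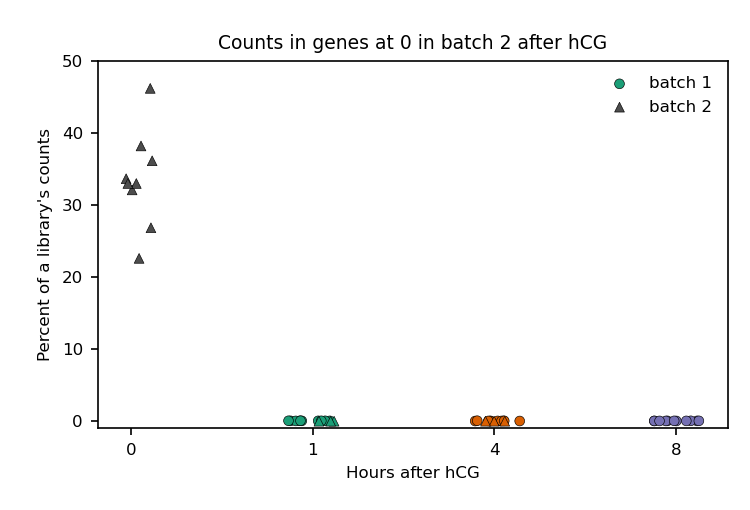
Percent of each library's counts, by hours after hCG, that fell in the 3332 genes with counts in batch 1 and 0 counts in the 6 batch 2 libraries at 1 h and 4 h (circles, batch 1; triangles, batch 2). The 9 libraries at 0 h lie between 22.6% and 46.2%, and no later library is above 0.0667%.

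The first principal components of the log2 counts per 1e+06 of the library size after TMM scaling (CPM) held 33.3% and 14.3% of the variance. On them the 0 h follicles lay apart from the others, the 3 batch 2 follicles at 1 h lay apart from the 10 of batch 1, and those at 4 h lay within the range of batch 1 except replicate 12. On component 1 replicate 12 stood at -33.7, just beyond the nearest batch 1 follicle of that time at -34.2. Of 8629 genes tested, 6883 (79.8%) changed over time in the joint test of the 4 times (edgeR adjusted p under 0.05). The fitted mean was highest at 0 h for 2782 of these, at 1 h for 1146, at 4 h for 1555 and at 8 h for 1400. Without the 3332 genes, 7067 of 8835 genes changed, of which 2499 were highest at 0 h and 1819 at 4 h.

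**Figure D2:**
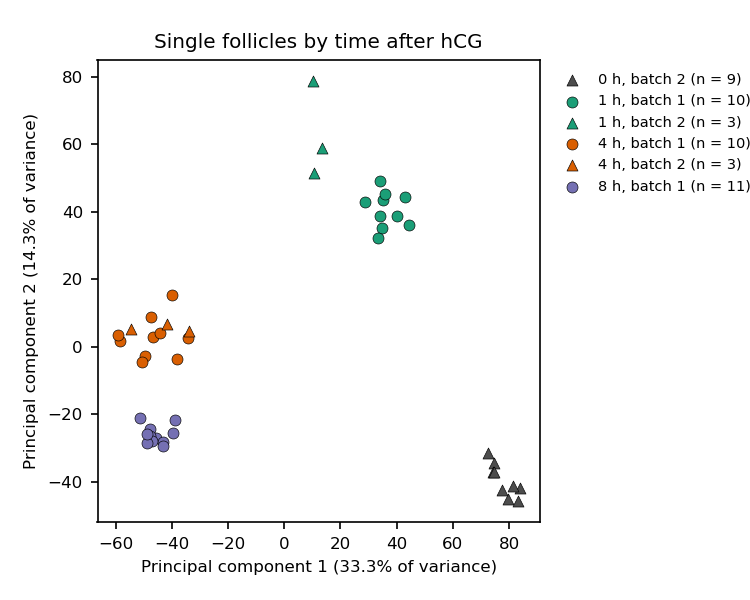
Principal components 1 and 2 (33.3% and 14.3% of variance) of log2 CPM, with each point a follicle, the color its hours after hCG and the symbol its batch. The 0 h follicles, all of batch 2, lie apart from the others, and the 3 batch 2 follicles at 1 h lie apart from the 10 of batch 1.

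At 1 h against 0 h (13 and 9 follicles), which asks what the first hour after hCG brings, transcription factors of the immediate early response led the rises. Nr4a1, an orphan nuclear receptor (ENSMUSG00000023034.7, chromosome 15 from 101254269 to 101274795, GRCm38), went from 17.0 ± 13.5 CPM (SD, n = 9) to 6417 ± 2785 CPM (SD, n = 13). Its log2 fold change was 8.49 ± 0.80 (SE, edgeR adjusted p = 4.1e-12), a 359-fold rise. Nr4a2 rose by 7.94 ± 0.74, Nr4a3 by 9.30 ± 0.68, and the AP-1 subunits Fosb and Junb by 7.30 ± 0.52 and 6.37 ± 0.51. Unless given otherwise, values beside genes are log2 fold changes ± SE, and genes said to have risen or fallen had an edgeR adjusted p under 0.05. Cxcl1, a chemokine that attracts neutrophils, rose by 8.01 ± 0.67, and F3, the tissue factor that starts coagulation, by 7.57 ± 0.57. Btg2, which restrains proliferation (7.38 ± 0.51), the kinase gene Sik1 (6.94 ± 0.53) and Ier3 (6.29 ± 0.45) rose as well. Star, which brings cholesterol into mitochondria for steroid synthesis (ENSMUSG00000031574.8, chromosome 8 from 25806555 to 25815982, GRCm38), rose by 6.11 ± 0.75 (SE, edgeR adjusted p = 1.0e-08). It went from 5.94 ± 4.73 CPM (SD, n = 9) to 438 ± 289 CPM (SD, n = 13).

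All 25 measured members of the immediate early list rose (camera adjusted p = 5.9e-37, and adjusted p = 2.4e-06 with an estimated correlation). Among them were Fos (2.21 ± 0.43) and Egr1 (3.91 ± 0.40), which encode transcription factors. Counts of members adjusted over the list alone were the same wherever no other count is given. Every list that camera called was called in the direction of most of its changed members. Of 15 genes for EGF ligands and feedback on the ERK kinases, 8 rose, 2 fell and 5 were not called (9 and 2 adjusted over the list alone, camera adjusted p = 0.00273, and adjusted p = 0.0424 with an estimated correlation). The ligands Ereg and Areg rose by 5.94 ± 1.03 and 4.71 ± 1.10. The receptor gene Egfr fell (-1.05 ± 0.37). Among 14 genes of inflammation and cytokines, 8 rose, 0 fell and 6 were not called (9 and 1 adjusted over the list alone, camera adjusted p = 1.2e-06, and adjusted p = 0.0424 with an estimated correlation). Cxcl2, a chemokine with 2 counts over the 9 follicles at 0 h, was 289-fold higher (counting interval 79.1 to 2406). Il6, a cytokine below the filter, had 0 counts at 0 h and 10 at 1 h and was at least 9.28-fold higher. Edn2, a vasoconstrictor peptide with 0 counts at 0 h, was at least 22.3-fold higher. The floor was 3 counts over the group, and intervals and floors cover counting error only. In the progesterone receptor network, 5 rose, 1 fell and 8 were not called (5 and 2 adjusted over the list alone, camera adjusted p = 0.0263, and adjusted p = 0.253 with an estimated correlation). Its rises included the protease gene Adamts1 (4.02 ± 0.51) and the transcription factor gene Runx1 (2.18 ± 0.54). Pgr itself was not called (2.00 ± 1.24, edgeR adjusted p = 0.207), but was with batch 2 alone (4.21, edgeR adjusted p = 0.00187) and with DESeq2 (3.45).

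In cumulus expansion, the swelling of the matrix around the oocyte, 3 rose, 0 fell and 8 were not called (camera adjusted p = 0.254). Ptgs2, which makes prostaglandins (5.28 ± 0.99), Tnfaip6, which links hyaluronan (4.27 ± 0.91), and the hyaluronan synthase Has2 (2.10 ± 0.79) rose. Has2 was not called without 1 h replicate 11 (1.38) or 12 (1.92), without the 5 libraries of 0 h marked "_ds" (1.32), in thinned counts (1.57) or with limma on log2(TPM + 1) (0.90). Ptx3 of the same matrix had 1 count over the 0 h follicles and 8 at 1 h, of which 4 were in replicate 12, a ratio of 22.3 at equal depth (counting interval 2.99 to 988). Among 11 prostaglandin genes 3 rose, 1 fell and 7 were not called (camera adjusted p = 0.558). Of 21 genes of luteinization and progesterone synthesis, 6 rose, 2 fell and 13 were not called (camera adjusted p = 0.0469, and adjusted p = 0.457 with an estimated correlation). Rgs2, a regulator of G protein signaling, rose (5.38 ± 0.39), and Fdxr, which passes electrons to steroid-making enzymes, fell (-1.53 ± 0.34). Cyp11a1, which makes pregnenolone from cholesterol, was not called (0.94 ± 0.64, edgeR adjusted p = 0.253), nor was the hormone receptor Lhcgr (-0.35 ± 0.73). Of 22 follicular phase granulosa genes, 1 rose, 7 fell and 14 were not called (camera adjusted p = 0.114). Cyp19a1, the aromatase of estrogen synthesis, was the one that rose (1.83 ± 0.42). The transcription factor genes Foxo1 (-2.09 ± 0.33) and Foxl2 (-2.46 ± 0.57), the cyclin Ccnd2 (-1.63 ± 0.37) and the receptor Fshr (-1.43 ± 0.40) fell. Sult1e1, the estrogen sulfotransferase, and Inhba, an inhibin subunit, were not called (2.02 ± 1.69 and -0.22 ± 0.48), although Sult1e1 was in batch 2 alone (4.30, edgeR adjusted p = 0.00489) and with DESeq2 (3.35, adjusted p = 0.0343).

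Cholesterol synthesis genes went both ways, as 7 rose, 5 fell and 10 were not called (7 and 6 adjusted over the list alone, camera adjusted p = 0.164). Insig1 (1.86 ± 0.27) and Idi1 (1.77 ± 0.30) rose and Ebp fell (-2.33 ± 0.50). Among proteases and their inhibitors 3 rose, 1 fell and 13 were not called (3 and 0 adjusted over the list alone, camera adjusted p = 0.0136, and adjusted p = 0.176 with an estimated correlation), and Plau, the urokinase plasminogen activator, rose by 4.81 ± 0.38. Of 27 cell cycle genes 0 rose, 8 fell and 19 were not called (0 and 7 adjusted over the list alone, camera adjusted p = 0.0285, and adjusted p = 0.567 with an estimated correlation), such as the replication helicase subunit Mcm6 (-1.69 ± 0.42). Among 12 heat shock genes 6 rose, 0 fell and 6 were not called (camera adjusted p = 3.7e-04, and adjusted p = 0.0750 with an estimated correlation). The chaperone genes Bag3 (2.23 ± 0.34) and Dnajb4 (2.23 ± 0.31) were among those that rose. For stress of protein folding and amino acid supply, 5 rose, 0 fell and 9 were not called (camera adjusted p = 3.7e-04, and adjusted p = 0.176 with an estimated correlation). Ppp1r15a (3.65 ± 0.32) and Dnajb9 (2.49 ± 0.28) rose. In meiotic arrest signaling 3 rose, 3 fell and 3 were not called (camera adjusted p = 0.254), with a median of -0.24, a mean of 0.25 and a test pointing up. Nppc, the granulosa signal that holds the oocyte in arrest, fell (-1.38 ± 0.44). In hypoxia and glycolysis 1 rose, 9 fell and 11 were not called (1 and 10 adjusted over the list alone, camera adjusted p = 0.181), and the mitophagy gene Bnip3 fell (-3.15 ± 0.66).

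Markers of other cell types moved as well. Of 6 smooth muscle markers 3 rose, 0 fell and 3 were not called (4 and 0 adjusted over the list alone, camera adjusted p = 0.00214, and adjusted p = 0.154 with an estimated correlation), with the actins Acta2 at 2.85 ± 0.48 and Actg2 at 2.40 ± 0.58. None of 14 theca and stroma markers (camera adjusted p = 0.207) and none of 7 oocyte markers (camera adjusted p = 0.250) was called. The endothelial marker Cdh5, the single member of its list that was measured, rose (1.98 ± 0.67). Lyz2, the single leukocyte marker measured, and the surface epithelium markers Krt8 and Krt18 were not called. Among 12 mitochondrially encoded genes 6 rose, 0 fell and 6 were not called (camera adjusted p = 0.00357, and adjusted p = 0.253 with an estimated correlation). The complex I subunits mt-Nd6 (0.94 ± 0.17) and mt-Nd2 (0.75 ± 0.23) were among those that rose.

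In all, 2985 genes changed at 1 h, of which 1071 rose and 1914 fell, and 1932 did so by 2-fold or more (edgeR adjusted p under 0.05). Without the set-apart genes 1241 rose and 1715 fell. Of the 10 largest falls under the rule for named genes, 7 belonged to the set-apart genes (fitted values from -15.43 to -17.06), among them Cxxc4, Ptgr2 and Pawr. The others were Mtmr4 (-4.23 ± 0.52, edgeR adjusted p = 9.3e-09), Tmem14c (-4.08 ± 0.50) and Ankmy2 (-3.64 ± 0.43). Without the set-apart genes the rule went on with Fen1, a nuclease of DNA replication (-3.53 ± 0.59), Polr3k, a subunit of RNA polymerase III (-3.38 ± 0.47), and Txnip, which binds thioredoxin (-3.36 ± 0.51). Batch 2 alone (3 and 9 follicles) called 1828 genes and gave the same sign for 2938 of 2947. Here and below, the libraries of a batch fitted alone are also in the main fit, so shared signs are no separate replication. Of the genes above batch 2 alone did not call Nppc (-0.73), Fshr (-1.04), Ccnd2 (-1.23), Egfr (-1.39), Fdxr (-1.30), Ebp (-1.37), Mcm6 (-1.19), Cdh5 (1.09), mt-Nd6 (0.89) or mt-Nd2 (0.24). Rises made up 35.9% of calls, 37.1% with RLE factors, 26.8% without the filter (1045 and 2854) and 51.5% in thinned counts (440 and 415). With limma on log2(TPM + 1), which changed the unit, the test and the genes tested (11834) together, 1926 rose and 2058 fell (48.3% rises), with all genes shifted by a median of 0.32. TPM were not scaled further, and the set-apart genes, high at 0 h alone, stayed in their totals. The weight of those genes at 0 h was therefore not removed from this shift.

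**Figure D3:**
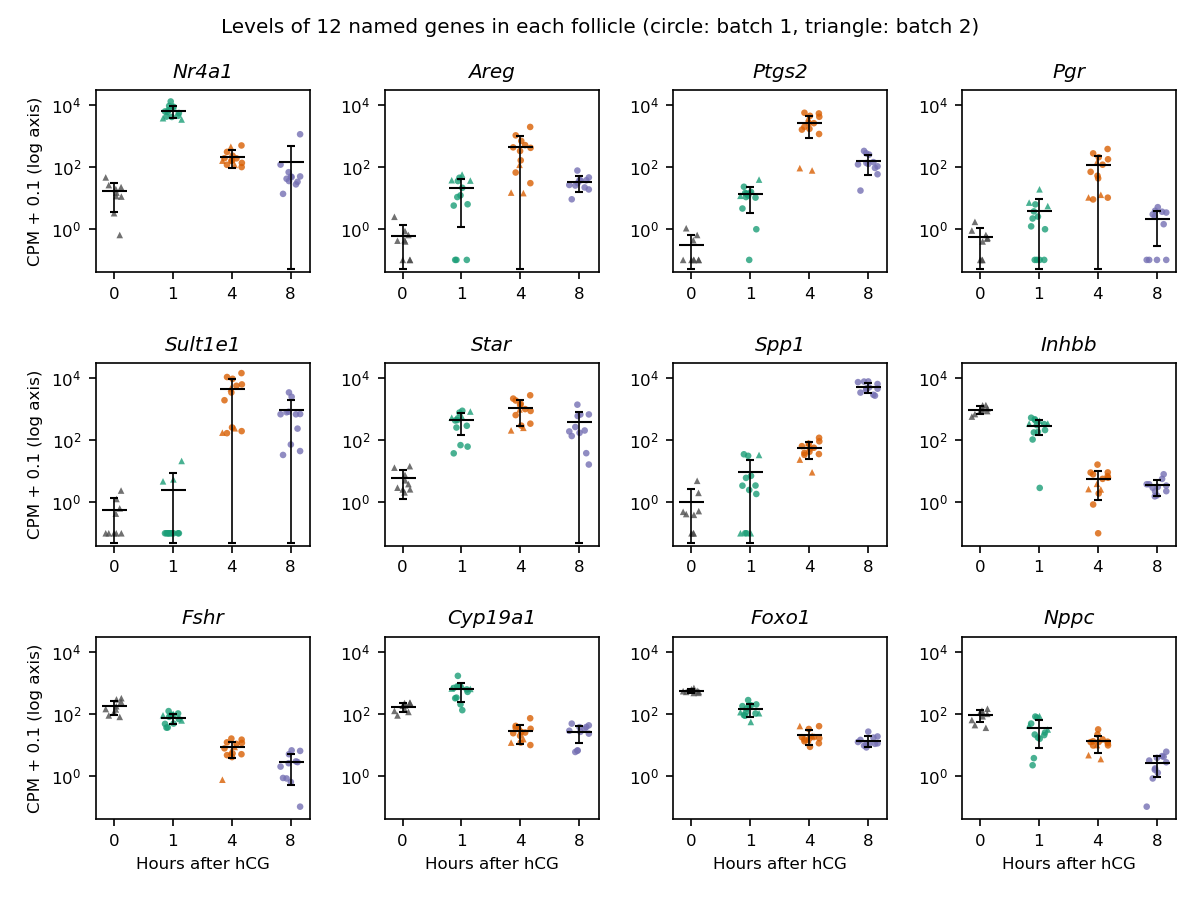
CPM (plus 0.1, log axis) of 12 genes in each of the 46 follicles, by hours after hCG (circles, batch 1, and triangles, batch 2), with black bars for the mean and SD of all follicles of a time (lower arms that would pass below 0 end at the axis). Nr4a1 peaks at 1 h, Ptgs2 and Pgr at 4 h and Spp1 at 8 h, while Inhbb, Fshr, Foxo1 and Nppc are lower at each later time.

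At 4 h against 0 h (13 and 9 follicles), which asks how follicles stand midway through the course, Ptgs2, Sult1e1, Serpinb2 and 3 ligands of the EGF family were among the genes that rose most. Ptgs2 (ENSMUSG00000032487.8, chromosome 1 from 150100031 to 150108227, GRCm38) went from 0.202 ± 0.341 CPM (SD, n = 9) to 2665 ± 1815 CPM (SD, n = 13). Its log2 fold change was 12.91 ± 0.93 (SE, edgeR adjusted p = 2.4e-16). This estimate rests mainly on the 3 batch 2 follicles at 4 h, which differed widely. Replicate 11 held far more Ptgs2 than replicates 12 and 13, with values given further on. Sult1e1 (ENSMUSG00000029272.8, chromosome 5 from 87575969 to 87591594, GRCm38), whose product inactivates estrogens, rose by 12.73 ± 1.37 (SE, edgeR adjusted p = 6.2e-11). Its level varied widely at 4 h (4471 ± 4760.4 CPM, SD, n = 13). Serpinb2, an inhibitor of plasminogen activators, had 0 counts in all 9 follicles at 0 h and was at least 1201-fold higher at 4 h. The EGF family ligands Btc (10.95 ± 0.75), Ereg (10.51 ± 1.05) and Areg (8.92 ± 1.09) rose. So did Tnfaip6 (10.41 ± 0.91), Cxcl1 (9.65 ± 0.73), F3 (9.34 ± 0.62) and the chromatin protein gene Hmga1 (8.97 ± 0.57).

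Of 11 cumulus expansion genes 7 rose, 2 fell and 2 were not called (camera adjusted p = 0.00784, and adjusted p = 0.0436 with an estimated correlation), with Has2 at 6.71 ± 0.66. Ptx3 was 1064-fold higher than its 1 count at 0 h (counting interval 191 to 42077). In the EGF and ERK list 9 rose, 2 fell and 4 were not called (camera adjusted p = 4.3e-04, and adjusted p = 0.0162 with an estimated correlation). All 14 measured genes of inflammation rose (camera adjusted p = 2.5e-07, and adjusted p = 0.0162 with an estimated correlation). Cxcl2 was 731-fold higher than its 2 counts at 0 h (counting interval 202 to 6038). Il6 and Edn2, with 0 counts at 0 h, were at least 34.2-fold and 12.9-fold higher. In the progesterone receptor network 8 rose, 3 fell and 3 were not called (camera adjusted p = 0.0318, and adjusted p = 0.335 with an estimated correlation). Pgr itself (7.17 ± 0.89), Runx1 (7.50 ± 0.46) and Adamts1 (2.69 ± 0.55) rose. Prostaglandin genes went both ways, as 6 rose, 3 fell and 2 were not called (camera adjusted p = 0.432). The receptor Ptger4 rose (3.61 ± 0.57), and Hpgd, which degrades prostaglandins, and Ptges, a prostaglandin E synthase, fell (-5.09 ± 0.51 and -2.56 ± 0.26). Of 21 luteinization genes 12 rose and 9 fell (camera adjusted p = 0.0837). Star rose by 7.41 ± 0.82 (SE, edgeR adjusted p = 1.6e-10) and Cyp11a1 by 1.73 ± 0.68 (edgeR adjusted p = 0.0289). Lhcgr (-2.94 ± 0.84) and Srd5a1, a steroid reductase (-3.74 ± 0.50), fell. Of 25 immediate early genes 14 rose, 3 fell and 8 were not called (camera adjusted p = 5.8e-05, and adjusted p = 0.136 with an estimated correlation). Ier3 (8.89 ± 0.50), Nr4a1 (3.59 ± 0.67) and Egr1 (2.80 ± 0.41) were higher than at 0 h. The AP-1 gene Fosl1 was 146-fold above its 3 counts at 0 h (counting interval 49.5 to 709). Jun (-1.62 ± 0.34) and Fos (-1.24 ± 0.44, edgeR adjusted p = 0.0149) were lower.

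Inhbb, an inhibin and activin subunit (ENSMUSG00000037035.5, chromosome 1 from 119415465 to 119422248, GRCm38), went from 971 ± 259.7 CPM (SD, n = 9) to 5.55 ± 4.43 CPM (SD, n = 13). Its log2 fold change was -7.34 ± 0.61 (SE, edgeR adjusted p = 2.9e-14). Of 22 follicular phase granulosa genes 0 rose, 15 fell and 7 were not called (camera adjusted p = 2.1e-06, and adjusted p = 0.0240 with an estimated correlation). Kctd14 (-6.56 ± 0.82), Foxo1 (-4.88 ± 0.35), Fshr (-4.55 ± 0.46), Cyp19a1 (-2.64 ± 0.48) and Ccnd2 (-2.06 ± 0.39) fell, and Inhba was not called (-0.63 ± 0.48). Outside this list Fam81a (-8.06 ± 0.58), Txnip (-6.86 ± 0.55), Bnip3 (-6.32 ± 0.80) and Cbs, an enzyme of cysteine synthesis (-5.43 ± 0.38), fell. In meiotic arrest signaling 2 rose, 6 fell and 1 was not called (camera adjusted p = 0.432), with falls of Nppc (-3.01 ± 0.49) and the cyclase gene Adcy9 (-4.42 ± 0.51). Of 27 cell cycle genes 0 rose, 16 fell and 11 were not called (camera adjusted p = 0.0167, and adjusted p = 0.689 with an estimated correlation). Mcm3 (-2.87 ± 0.44) and the mitotic cyclin Ccnb2 (-2.86 ± 0.44) were among them.

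In cholesterol synthesis 3 rose, 12 fell and 7 were not called (camera adjusted p = 0.0837). Among proteases and inhibitors 8 rose, 3 fell and 6 were not called (camera adjusted p = 0.0837), with rises of Plau (6.07 ± 0.38) and the metalloprotease inhibitor Timp1 (4.74 ± 0.45). In hypoxia and glycolysis 4 rose, 12 fell and 5 were not called (camera adjusted p = 0.243), with rises of the hexokinase Hk2 (2.62 ± 0.43) and the glucose transporter Slc2a1 (2.40 ± 0.38). Among heat shock genes 9 rose and 3 fell (camera adjusted p = 0.00672, and adjusted p = 0.184 with an estimated correlation). Hsph1 rose (2.30 ± 0.28), and Hspa1a, which shares reads with a near-identical copy, fell (-4.55 ± 0.83). Genes of folding and amino acid stress were split, as 3 rose, 5 fell and 6 were not called (camera adjusted p = 0.923). Asns, which makes asparagine (3.99 ± 0.38), and its activator Atf4 (2.49 ± 0.18) rose, and Herpud1 fell (-2.36 ± 0.29). Of 14 theca and stroma markers 0 rose, 4 fell and 10 were not called (camera adjusted p = 0.258). Cyp17a1, the androgen synthesis enzyme of theca cells (-3.39 ± 0.77), and Aldh1a1 (-3.25 ± 0.69) fell. Among smooth muscle markers 3 rose, 1 fell and 2 were not called (camera adjusted p = 0.376), with rises of Tagln (2.99 ± 0.64) and Acta2 (2.10 ± 0.46). No oocyte marker was called (camera adjusted p = 0.953), with a median of -0.17, a mean of 0.01 and a test pointing up. Cdh5, Lyz2, Krt8 and Krt18 were not called either. Mitochondrially encoded genes (2 rose, 3 fell and 7 were not called, camera adjusted p = 0.953) had a median of 0.05, a mean of -0.27 and a test pointing up. Among them mt-Nd3 fell (-1.37 ± 0.29).

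At 4 h, 4673 genes changed, of which 1894 rose and 2779 fell, 3260 of them by 2-fold or more (edgeR adjusted p under 0.05). With the set-apart genes left out 2357 rose and 2450 fell (49.0% rises against 40.5%), and 840 rose and 820 fell in thinned counts. Under the rule, 7 of the 10 largest falls (fitted values from -16.28 to -18.78) belonged to the set-apart genes. Batch 2 alone (3 and 9 follicles) called 3705 genes, with the same sign for 4593 of 4598, and did not call Fos (-0.86, edgeR adjusted p = 0.0949) or mt-Nd3 (-0.75). With limma on log2(TPM + 1), 3348 rose and 2515 fell (57.1% rises against 40.5%) and on log2(TPM + 0.1) 2956 and 2523 (54.0%), all genes being shifted by medians of 0.51 and 0.55. The TPM totals at 0 h included the set-apart genes, so these shifts cannot be told apart from the weight of those genes.

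At 8 h against 0 h (11 and 9 follicles), which asks how follicles differ late in the course, Spp1 led the rises. Spp1, which encodes the secreted protein osteopontin (ENSMUSG00000029304.14, chromosome 5 from 104435118 to 104441050, GRCm38), went from 0.905 ± 1.58 CPM (SD, n = 9) to 5191 ± 1915 CPM (SD, n = 11). Its log2 fold change was 12.22 ± 0.81 (SE, edgeR adjusted p = 2.6e-17). Serpinb2 was at least 1319-fold higher than its 0 counts at 0 h, and Ptx3 1366-fold higher than its 1 count (counting interval 245 to 54006). Sult1e1 (10.44 ± 1.46), Ptgs2 (8.73 ± 0.99), Ier3 (8.52 ± 0.52) and Hmga1 (8.28 ± 0.60) rose. Tnfaip6 (8.12 ± 0.96), the stress gene Nupr1 (8.11 ± 0.57) and Btc (8.10 ± 0.82) rose too. Outside the set-apart genes, the largest falls under the rule were those of Inhbb (-8.29 ± 0.67, edgeR adjusted p = 2.5e-14) and Hsd11b2, which inactivates glucocorticoids (-7.97 ± 0.67). Fam81a (-7.71 ± 0.69), Cbs (-7.50 ± 0.48), Hpgd (-6.94 ± 0.64) and the carbonic anhydrase Car14 (-6.79 ± 0.52) followed.

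Of 22 follicular phase granulosa genes 1 rose, 18 fell and 3 were not called (camera adjusted p = 2.1e-09, and adjusted p = 0.00978 with an estimated correlation). Fshr (ENSMUSG00000032937.5, chromosome 17 from 88984952 to 89200675, GRCm38) fell by 6.13 ± 0.55 and Foxo1 by 5.52 ± 0.40. Kctd14 (-6.55 ± 0.91), Inhba (-3.33 ± 0.59), Ccnd2 (-3.26 ± 0.45) and Cyp19a1 (-2.74 ± 0.54) fell as well. In cumulus expansion 8 rose, 1 fell and 2 were not called (camera adjusted p = 0.00159, and adjusted p = 0.0193 with an estimated correlation), with Has2 at 3.32 ± 0.77. In the EGF and ERK list 10 rose, 1 fell and 4 were not called (camera adjusted p = 0.00681, and adjusted p = 0.0549 with an estimated correlation). Ereg (7.82 ± 1.11) and Areg (5.16 ± 1.21) rose and the ligand Hbegf fell (-5.39 ± 0.58). Of 21 luteinization genes 9 rose, 4 fell and 8 were not called (camera adjusted p = 0.0125, and adjusted p = 0.407 with an estimated correlation). Runx1 (7.34 ± 0.51), Runx2, a transcription factor gene (6.73 ± 0.55), and Star (5.93 ± 0.85) rose, and Lhcgr fell (-3.60 ± 0.94). Cyp11a1 was not called (1.23 ± 0.76, edgeR adjusted p = 0.188). In the progesterone receptor network 7 rose, 3 fell and 4 were not called (camera adjusted p = 0.0376, and adjusted p = 0.376 with an estimated correlation). Snap25, a gene of vesicle fusion, was 217-fold above its 1 count at 0 h (counting interval 38.4 to 8595). Adamts1 rose (3.97 ± 0.60), the nuclear receptor gene Pparg fell (-3.99 ± 0.55), and Pgr was not called (1.39 ± 1.18, edgeR adjusted p = 0.344). Edn2, with 1 count at 8 h and 0 at 0 h, gives no ratio.

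Among genes of inflammation 10 rose, 0 fell and 4 were not called (11 and 0 adjusted over the list alone, camera adjusted p = 4.7e-04, and adjusted p = 0.133 with an estimated correlation). Tnfrsf12a, a receptor of the tumor necrosis factor family, rose (5.62 ± 0.35). Cxcl5 and Il6, with 0 counts at 0 h, were at least 18.3-fold and 14.3-fold higher. Among proteases and inhibitors 10 rose, 3 fell and 4 were not called (10 and 4 adjusted over the list alone, camera adjusted p = 0.0125, and adjusted p = 0.228 with an estimated correlation). Timp1 (6.25 ± 0.52) and Plau (5.66 ± 0.42) rose and Adamts5 fell (-3.29 ± 0.41). In cholesterol synthesis 9 rose, 3 fell and 10 were not called (10 and 3 adjusted over the list alone). The camera adjusted p was 0.0376, and 0.644 with an estimated correlation. Of 27 cell cycle genes 1 rose, 15 fell and 11 were not called (camera adjusted p = 0.00689, and adjusted p = 0.596 with an estimated correlation), with Ccnb2 at -3.82 ± 0.51. Of 25 immediate early genes 9 rose, 4 fell and 12 were not called (10 and 5 adjusted over the list alone, camera adjusted p = 0.0376, and adjusted p = 0.533 with an estimated correlation). Nr4a1 was higher (3.03 ± 0.77, and 1.57 ± 0.52 without replicate 4, which held 1122 CPM against 13.4 to 118 in the other 10 follicles), Fos lower (-2.70 ± 0.54), and Egr1 not called (0.90 ± 0.46, edgeR adjusted p = 0.104). Among prostaglandin genes 5 rose, 3 fell and 3 were not called (camera adjusted p = 0.919). In hypoxia and glycolysis 6 rose, 2 fell and 13 were not called (camera adjusted p = 0.283), with a rise of the oxygen sensor Egln3 (3.28 ± 0.71). In meiotic arrest signaling 1 rose, 5 fell and 3 were not called (camera adjusted p = 0.0861), with falls of Nppc (-5.16 ± 0.59) and its receptor Npr2 (-4.46 ± 0.33). Heat shock genes (4 rose, 2 fell and 6 were not called, camera adjusted p = 0.189) had a median of 0.45, a mean of -0.14 and a test pointing up. For folding and amino acid stress 3 rose, 5 fell and 6 were not called (camera adjusted p = 0.611).

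Theca and stroma markers held no rise, as 0 rose, 6 fell and 8 were not called (camera adjusted p = 0.0768). Cyp17a1 (-5.24 ± 0.98) and Aldh1a1 (-5.57 ± 0.81) were among those that fell. Among smooth muscle markers 0 rose, 2 fell and 4 were not called (camera adjusted p = 0.799). Of the mitochondrially encoded genes 0 rose, 4 fell and 8 were not called (0 and 3 adjusted over the list alone, camera adjusted p = 0.867), while 3 rose and 2 fell in the fit without the set-apart genes. No oocyte marker was called (camera adjusted p = 0.387), with a median of -0.06, a mean of 0.36 and a test pointing up. The surface epithelium marker Krt18 rose (2.39 ± 0.91, edgeR adjusted p = 0.0282), and Krt8, Cdh5 and Lyz2 were not called.

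In total 3892 genes changed at 8 h, of which 1512 rose and 2380 fell, 3021 of them by 2-fold or more (edgeR adjusted p under 0.05). The counts were 1914 and 2110 without the set-apart genes (47.6% rises). Of the 10 largest falls under the rule, 7 belonged to the set-apart genes (fitted values from -16.39 to -18.70). No batch holds both times, so each fitted value joins differences within the batches and assumes an equal batch shift at every time. From 1 h to 4 h the change differed between the batches for 296 of 5820 genes, so the assumption failed for them. Btc, Areg, Hmga1, Ier3, Adamts1, Tnfrsf12a and Tubb6, given at 8 h, were among them. For other genes the assumption stays open, as the test found 47.1% of simulated 4-fold and 1.85% of 2-fold changes. The ratios and bounds of Serpinb2, Ptx3, Snap25, Cxcl5 and Il6 set pooled counts of batch 1 against batch 2 without a batch term. Rises made up 38.8% of calls, against 63.3% with limma on log2(TPM + 1) (3368 and 1950) and 60.6% on log2(TPM + 0.1) (3019 and 1960), where all genes were shifted by medians of 0.61 and 0.67. These shifts too cannot be told apart from the weight of the set-apart genes in the TPM totals at 0 h.

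**Figure D4:**
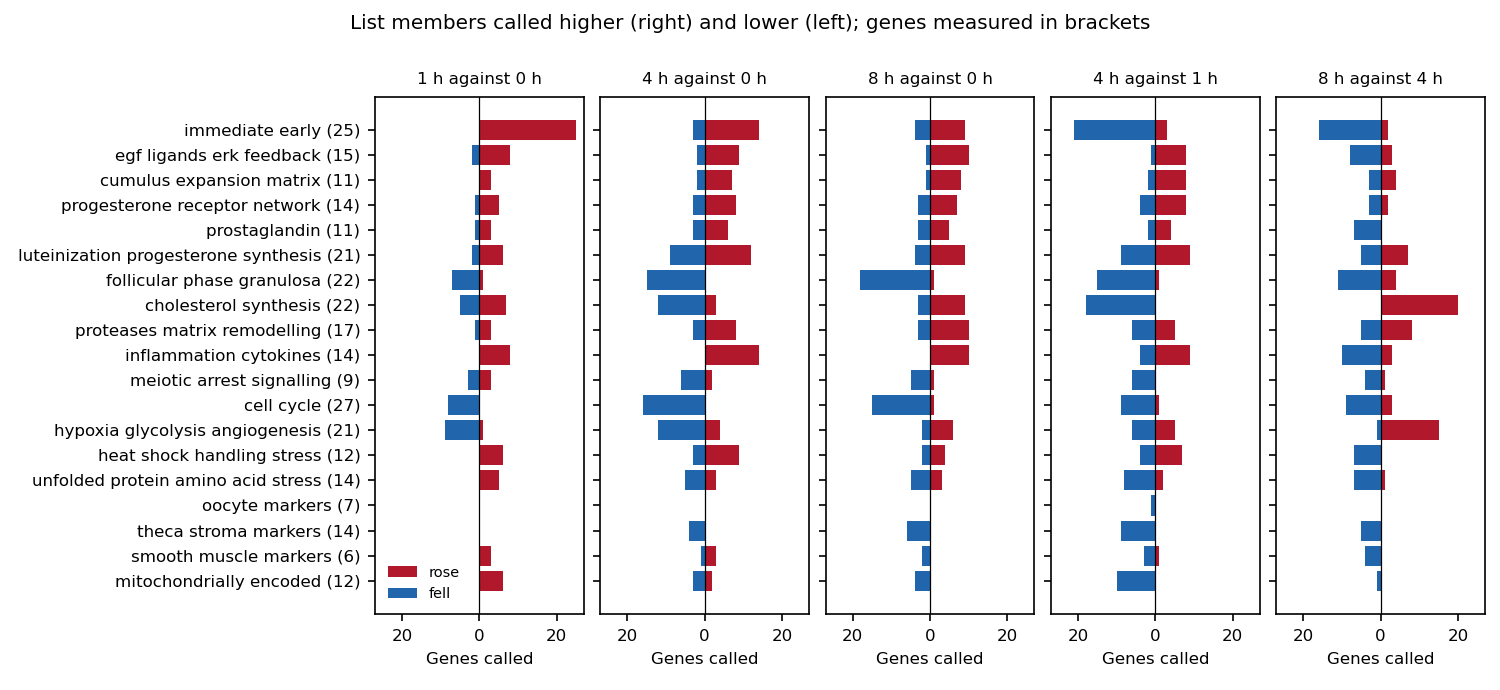
Number of measured genes of 19 fixed gene lists called higher (red, to the right) or lower (blue, to the left) in each comparison, with the number of genes measured in brackets. Immediate early genes rise at 1 h and mostly fall by 4 h, and 20 of 22 cholesterol synthesis genes rise between 4 h and 8 h.

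From 1 h to 4 h (13 and 13 follicles), a step present in both batches, Sult1e1 (10.71 ± 1.02), Btc (8.71 ± 0.54), Serpinb2 (8.01 ± 0.78) and Ptgs2 (7.63 ± 0.57) had the largest rises under the rule. Ifi202b, an interferon-inducible gene of a family of close copies and uncertain for that reason, followed (6.81 ± 0.56). The largest falls under the rule, which asks for a mean log2 CPM of at least 3, were those of Fosb (-8.34 ± 0.43), Nr4a2 (-6.95 ± 0.55), Adck3 (-5.77 ± 0.41), Inhbb (-5.60 ± 0.39) and Ell2, an elongation factor of RNA polymerase II (-5.38 ± 0.35). Immediate early genes turned down as a list, since 3 rose, 21 fell and 1 was not called (camera adjusted p = 1.7e-09, and adjusted p = 0.0265 with an estimated correlation). Nr4a3 (-7.41 ± 0.47, below that level), Nr4a1 (-4.90 ± 0.54), Fos (-3.45 ± 0.33) and Egr1 (-1.11 ± 0.29) fell. Pgr (5.17 ± 0.64), Has2 (4.61 ± 0.46), Tnfaip6 (6.14 ± 0.58) and Ptx3 (5.38 ± 0.64) rose in the same step. Areg (4.21 ± 0.64), Ereg (4.57 ± 0.60), Runx1 (5.31 ± 0.33) and Star (1.30 ± 0.50, edgeR adjusted p = 0.0247) rose too, and Adamts1 fell (-1.33 ± 0.38).

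Follicular phase granulosa genes fell as a list, since 1 rose, 15 fell and 6 were not called (2 and 16 adjusted over the list alone, camera adjusted p = 6.2e-07, and adjusted p = 0.0265 with an estimated correlation). Cyp19a1 (-4.47 ± 0.35), Fshr (-3.12 ± 0.31), Foxo1 (-2.79 ± 0.23) and, of the luteinization list, Lhcgr (-2.59 ± 0.58) fell. In cholesterol synthesis 0 rose, 18 fell and 4 were not called (camera adjusted p = 9.6e-05, and adjusted p = 0.366 with an estimated correlation), such as the mevalonate pathway kinases Pmvk (-2.64 ± 0.35) and Mvk (-2.44 ± 0.36). In cumulus expansion 8 rose, 2 fell and 1 was not called (camera adjusted p = 0.00631, and adjusted p = 0.0344 with an estimated correlation). In the EGF and ERK list 8 rose, 1 fell and 6 were not called (camera adjusted p = 0.0159, and adjusted p = 0.0944 with an estimated correlation). With a term for the library sets, 4 lists were called lower in this step and 0 higher, so neither rise was called. Among genes of inflammation 9 rose, 4 fell and 1 was not called (camera adjusted p = 0.0159, and adjusted p = 0.366 with an estimated correlation), while a term for the library sets turned the direction of the list (adjusted p = 0.730). Cxcl5 was 50.0-fold above its 2 counts at 1 h (counting interval 13.7 to 415) and Il6ra, the interleukin 6 receptor gene, 35.7-fold above its 1 count (6.27 to 1425). In meiotic arrest signaling 0 rose, 6 fell and 3 were not called (camera adjusted p = 0.0159, and 0.0944 with an estimated correlation). Adcy9 (-2.84 ± 0.36) and Nppc (-1.64 ± 0.33) fell. For folding and amino acid stress 2 rose, 8 fell and 4 were not called (2 and 9 adjusted over the list alone). The camera adjusted p was 0.0132, and 0.373 with an estimated correlation. Herpud1 (-4.08 ± 0.22) and Ppp1r15a (-3.52 ± 0.25) fell. Among theca and stroma markers 0 rose, 9 fell and 5 were not called (camera adjusted p = 0.00820, and 0.429 with an estimated correlation). Cyp17a1 fell (-3.15 ± 0.55). Among mitochondrially encoded genes 0 rose, 10 fell and 2 were not called (camera adjusted p = 0.00820, and 0.366 with an estimated correlation). Of them mt-Nd3 fell (-1.08 ± 0.21). Their share of counts fell in batch 1 (12.4% to 9.27%) but rose in batch 2 (9.68% to 12.03%), and the term for the library sets turned the list (adjusted p = 0.322).

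The progesterone receptor network was not called as a list, as 8 rose, 4 fell and 2 were not called (camera adjusted p = 0.229). For prostaglandins 4 rose, 2 fell and 5 were not called (camera adjusted p = 0.627), and Pla2g4a, which frees arachidonic acid, rose (3.86 ± 0.30). For luteinization 9 rose, 9 fell and 3 were not called (camera adjusted p = 0.591). For proteases and inhibitors 5 rose, 6 fell and 6 were not called (5 and 7 adjusted over the list alone, camera adjusted p = 0.937). For the cell cycle 1 rose, 9 fell and 17 were not called (1 and 8 adjusted over the list alone, camera adjusted p = 0.456). For hypoxia and glycolysis 5 rose, 6 fell and 10 were not called (camera adjusted p = 0.627). Heat shock genes (7 rose, 4 fell and 1 was not called, camera adjusted p = 0.467) had a median of 0.33, a mean of -0.48 and a test pointing up, with falls of Hspa1a (-4.90 ± 0.60) and Dnajb4 (-4.11 ± 0.24). For smooth muscle markers 1 rose, 3 fell and 2 were not called (1 and 4 adjusted over the list alone, camera adjusted p = 0.142). Of 7 oocyte markers Tle6 fell (-1.16 ± 0.46, edgeR adjusted p = 0.0296) and 6 were not called (0 fell adjusted over the list alone, camera adjusted p = 0.456). Cdh5 (-1.56 ± 0.48) and Lyz2 (-1.87 ± 0.75) fell, and Krt8 and Krt18 were not called. Lyz2 was not called with DESeq2 (-1.55), without the filter (-1.61), with the term for the library sets (-0.35) or in batch 2 alone (-0.27). Cdh5 was not called with that term (-0.11) or with limma on log2(TPM + 1) (-0.85) and log2(TPM + 0.1) (-1.07).

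In this step 4733 genes changed (edgeR adjusted p under 0.05), of which 2241 rose and 2492 fell, 2442 of them by 2-fold or more. The majority turned without the set-apart genes (2557 rose and 2208 fell), without the filter (2933 and 2257) and in thinned counts (988 and 910). In batch 1 the 4 h follicles came from a plate of their own and the 1 h follicles from another, and a term for the library sets called 2054 genes (1134 rose and 920 fell). Batch 1 alone called 3545 genes and batch 2 alone (3 and 3 follicles) 701, with the same sign for 3565 of 3565 and 3147 of 3460 genes. In batch 2 alone the values of Areg (0.16), Ereg (1.85), Pgr (2.5), Tnfaip6 (4.24) and Lyz2 (-0.27) were not called, and those of Star (-0.43) and mt-Nd3 (0.30) had the other sign. Rises made up 47.3% of calls, against 63.0% with limma on log2(TPM + 1) (3270 and 1923) and 66.1% on log2(TPM + 0.1) (3321 and 1703), with shifts of 0.19 and 0.22.

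The step from 1 h to 4 h was then tested for a difference between the batches in the 26 follicles of both times. Of 5820 genes 296 differed (edgeR adjusted p under 0.05), with 1164 at an unadjusted p under 0.05. The change was higher in batch 2 for 186 of the 296 and lower for 110, against 33 and 51 in thinned counts. For Btc the log2 change was 10.31 in batch 1 and 5.71 in batch 2, a difference of -4.60 ± 1.17 (SE, edgeR adjusted p = 0.0186). For Areg (ENSMUSG00000029378.5, chromosome 5 from 91139599 to 91148432, GRCm38) it was 5.28 and 0.16, a difference of -5.16 ± 1.37 (SE, edgeR adjusted p = 0.0233). For Hmga1 it was 6.76 and 3.72, a difference of -3.06 ± 0.56 (SE, edgeR adjusted p = 0.00157).

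From 4 h to 8 h (13 and 11 follicles), the largest rises under the rule were those of Spp1 (6.48 ± 0.47), the carbonic anhydrase Car12 (4.50 ± 0.38) and Dhrs3, an enzyme of retinol metabolism (3.98 ± 0.45). Speer4b (3.84 ± 0.50) and Speer4a (3.83 ± 0.58) followed, which belong to a family of near-identical copies and are uncertain. Cxcl1 (ENSMUSG00000029380.11, chromosome 5 from 90891241 to 90893115, GRCm38) fell by 5.92 ± 0.51. Ifi202b (-5.49 ± 0.48), Flrt3 (-5.26 ± 0.44), Pxdc1 (-4.81 ± 0.41) and Lrrtm3 (-4.73 ± 0.37) had the next falls under the rule, while Cxcl2 and Pgr, below its level, are given further on. Genes that had risen by 4 h came down, among them Pgr (-5.78 ± 0.61), Ptgs2 (-4.18 ± 0.49), Areg (-3.76 ± 0.57) and Has2 (-3.39 ± 0.41). Ereg (-2.70 ± 0.53), Sult1e1 (-2.30 ± 0.68), Tnfaip6 (-2.29 ± 0.49) and Star (-1.48 ± 0.51, edgeR adjusted p = 0.0167) came down too. Edn2 went from 39 counts to 1 and was 35.3-fold lower at equal depth (counting interval 5.97 to 1429). Ptx3 was not called (0.43 ± 0.37), and Adamts1 rose (1.28 ± 0.38), but was not called in batch 1 alone (1.03, edgeR adjusted p = 0.0566) or with limma on log2 TPM (0.90 with either pseudocount).

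In cholesterol synthesis 20 rose, 0 fell and 2 were not called (camera adjusted p = 5.4e-10, and 0.192 with an estimated correlation). Acat2 (3.06 ± 0.25) and Lss, the lanosterol synthase (2.47 ± 0.17), rose. In hypoxia and glycolysis 15 rose, 1 fell and 5 were not called (16 and 2 adjusted over the list alone). The camera adjusted p was 1.4e-04, and 0.383 with an estimated correlation. Bnip3 (2.88 ± 0.47) and the glycolytic enzyme Pfkl (2.59 ± 0.36) rose. For inflammation 3 rose, 10 fell and 1 was not called (3 and 11 adjusted over the list alone), with Cxcl2 at -7.09 ± 0.73. The camera adjusted p was 2.1e-04, and 0.192 with an estimated correlation. Of 25 immediate early genes 2 rose, 16 fell and 7 were not called (camera adjusted p = 1.4e-04, and adjusted p = 0.192 with an estimated correlation). Myc (-3.21 ± 0.31), Egr3 (-2.83 ± 0.25), Egr1 (-1.90 ± 0.31) and Fos (-1.46 ± 0.37) fell, and Nr4a1 was not called (-0.55 ± 0.51). Without 8 h replicate 4 (1122 CPM) Nr4a1 fell by 2.14 ± 0.37, and it was also called lower with the replicate block (-1.40) and with limma on log2(TPM + 1) (-1.65) and log2(TPM + 0.1) (-1.69). In the EGF and ERK list 3 rose, 8 fell and 4 were not called (camera adjusted p = 0.0276, and adjusted p = 0.192 with an estimated correlation), with a fall of the feedback inhibitor Spry2 (-3.64 ± 0.35). Among heat shock genes 0 rose, 7 fell and 5 were not called (camera adjusted p = 0.0115, and adjusted p = 0.211 with an estimated correlation), with Hsph1 at -1.32 ± 0.22.

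Among prostaglandin genes 0 rose, 7 fell and 4 were not called (1 and 7 adjusted over the list alone, camera adjusted p = 0.0600). Of the follicular phase granulosa genes 4 rose, 11 fell and 7 were not called (camera adjusted p = 0.0600). Inhba (-2.69 ± 0.38), Nap1l5 (-3.03 ± 0.45), the activin antagonist Fst (-2.74 ± 0.34) and Fshr (-1.58 ± 0.39) fell. Ccnd2 (-1.20 ± 0.28) and Foxo1 (-0.63 ± 0.25, edgeR adjusted p = 0.0370) fell too, and Igfbp5 rose (3.33 ± 0.48). Foxo1 was not called in 12 alternatives, among them batch 1 alone (-0.50, edgeR adjusted p = 0.105), no filter (-0.65) and limma on log2(TPM + 1) (-0.35). In luteinization 7 rose, 5 fell and 9 were not called (camera adjusted p = 0.344), with a rise of Runx2 (2.27 ± 0.28). Among proteases and inhibitors 8 rose, 5 fell and 4 were not called (9 and 5 adjusted over the list alone, camera adjusted p = 0.289). In the cell cycle list 3 rose, 9 fell and 15 were not called (camera adjusted p = 0.390). Cumulus expansion genes (4 rose, 3 fell and 4 were not called, camera adjusted p = 0.937) had a median of 0.43, a mean of -0.33 and a test pointing up. The progesterone receptor network (2 rose, 3 fell and 9 were not called, camera adjusted p = 0.990) had a median of 0.28, a mean of -0.38 and a test pointing up. In it Fkbp5 rose (3.13 ± 0.30) and Pparg fell (-4.17 ± 0.38). In meiotic arrest signaling 1 rose, 4 fell and 4 were not called (camera adjusted p = 0.0682), with falls of Npr2 (-2.80 ± 0.23) and Nppc (-2.15 ± 0.42). For folding and amino acid stress 1 rose, 7 fell and 6 were not called (camera adjusted p = 0.0737), with Atf4 at -1.56 ± 0.15. Among smooth muscle markers 0 rose, 4 fell and 2 were not called (camera adjusted p = 0.0600), with Tagln at -3.98 ± 0.56. Among theca and stroma markers 0 rose, 5 fell and 9 were not called (camera adjusted p = 0.289), with a fall of Insl3, a theca hormone (-2.38 ± 0.75). Mitochondrially encoded genes (0 rose, 1 fell and 11 were not called, camera adjusted p = 0.650) had a median of -0.06, a mean of 0.03 and a test pointing down. No oocyte marker was called (camera adjusted p = 0.228), Krt18 rose (1.58 ± 0.44), and Krt8, Cdh5 and Lyz2 were not called.

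Between 4 h and 8 h 3567 genes changed (edgeR adjusted p under 0.05), of which 1706 rose and 1861 fell (1626 and 1956 without the set-apart genes), 1471 of them by 2-fold or more. Batch 1 alone, which holds all 8 h follicles, called 3766, with the same sign for 3288 of 3288 genes. Rises were the majority with RLE factors (1819 and 1775), DESeq2 (1952 and 1884), no batch term (1946 and 1871) and limma on log2(TPM + 1) (1881 and 1390) and log2(TPM + 0.1) (1578 and 1207). All 4 h follicles of batch 1 came from a plate that held no other time, and a term for the plates gave 1446 genes (548 rose and 898 fell), with uncalled values of the other sign for Areg (0.97), Ereg (0.47), Star (0.50) and Sult1e1 (6.31). The term also ended the calls of Pgr (-2.00), Ptgs2 (-1.87), Has2 (-1.17), Tnfaip6 (-0.01), Egr1 (-0.84), Fshr (-0.53), Ccnd2 (-0.37), Nppc (-0.53), Ifi202b (-2.92), Pxdc1 (-2.00), Car12 (3.18), Speer4a (2.77), Pfkl (2.14), Nap1l5 (-2.18), Fst (-0.96), Insl3 (-3.51), Spry2 (-1.78), Runx2 (2.59) and Krt18 (2.90).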

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

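The tests of the loss of transcripts, of batch 2 libraries other than 1 h replicate 13, of theca cells behind the spread of Star and of theca cells behind its rise were chosen after the result was seen.

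At 0 h, 32 named genes had a library far from the other 8, where chance flags about 1 in 20 groups of normally distributed values and every group with counts in 1 library alone, such as Cxcl2, Ptx3 and Snap25. Values are CPM with the next value in parentheses. Replicate 3 was highest for Ankmy2 at 134.9 (54.0), Car12 at 46.6 (20.3), Ccdc152 at 166 (73.9), Ell2 at 12.3 (6.10), Has2 at 4.82 (2.05), Ifi202b at 2.68 (0.880), Pank1 at 18391 (10674), Ptger4 at 2.68 (1.17), Pxdc1 at 2.68 (1.27), Snap25 at 0.535 (0), Spp1 at 4.82 (1.90) and Spry2 at 68.5 (16.8). Replicate 1 was highest for Areg at 2.36 (0.750), Btg2 at 128 (46.1), Cxcl1 at 21.2 (2.25), Cxcl2 at 0.785 (0), Ereg at 1.18 (0.535), Errfi1 at 56.5 (32.6), F3 at 8.24 (2.35) and Nr4a3 at 2.36 (0.317). In replicate 7 Cdh5 stood at 25.03 (9.22), Egr1 at 296 (169.9), Igfbp5 at 90.0 (40.2), Myc at 73.2 (29.8), Pgr at 1.58 (0.785) and Txnip at 697 (349). The other libraries that stood apart were replicate 8 for Aldh1a1 at 2242 (908), Insl3 at 134 (54.1) and Lyz2 at 162 (69.6), replicate 9 for Krt18 at 6.21 (2.53) and Ptx3 at 0.621 (0), and replicate 5 for Lhcgr at 329 (163).

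Among 106 named genes tested, 12 had a log2 change from 1 h to 4 h that differed between the batches (edgeR interaction test), given here as batch 2 minus batch 1 ± SE. The change was lower in batch 2 for Areg by -5.16 ± 1.37, Btc by -4.60 ± 1.17, Hmga1 by -3.06 ± 0.56, Cxcl1 by -2.82 ± 0.61, Ier3 by -2.66 ± 0.51, Adamts1 by -2.39 ± 0.65, Spry2 by -2.15 ± 0.54, Bag3 by -1.97 ± 0.56, Tubb6 by -1.57 ± 0.39 and Tnfrsf12a by -1.49 ± 0.35. For Asns (2.01 ± 0.59) and mt-Nd3 (1.74 ± 0.44) it was higher in batch 2, and adjusted p ranged from 0.00157 for Hmga1 to 0.0432 for Asns.

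The 3332 genes with counts in batch 1 and 0 counts in the 6 batch 2 libraries after hCG held 22.6% to 46.2% of the counts at 0 h, and 180 of them had a 0 h mean above 1000. Loss of the transcripts within 1 h of hCG is argued against, since 0 of 5803 genes counted in 1 to 4 of the 6 libraries had such a mean (Fisher's exact test, two-sided, p = 6.2e-81). Batch adjustment of the counts may account for the pattern. For 300 genes the deposited counts were set to 0 in those libraries, and ComBat-seq was run with time as the group. It raised 94% of these genes by 10-fold or more at 0 h (282 of 300, against 0 of 300 left as they were). The counts had already been adjusted once, with settings that are not stated, so this was a second adjustment. In the authors' deposited table, 192 of the 193 falls of more than 1000-fold at 1 h, 270 of 271 at 4 h and 251 of 252 at 8 h belonged to these genes. Reads before adjustment are not in the deposited tables, so the level of these genes at 0 h stays open.

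Differences from 1 h to 4 h were smaller in batch 2, with a slope of 0.698 on those of batch 1 across 2796 genes, which are not independent replicates (r = 0.77, 75.7% of signs shared). A single outlying library is argued against by slopes of 0.679 without 1 h replicate 13 and of 0.611 to 0.739 without each of the other 5, and lower depth by a slope of 0.700 with all 26 libraries thinned to the same total. Error between follicles in the batch 1 differences is argued against too. In 50 draws, 3 against 3 batch 1 libraries gave slopes on the other 7 against 7 of 0.821 to 1.04. The 2.5% point of these slopes was 0.871. Every draw set the same plates of batch 1 against each other, so a plate difference within the batch 1 values was not tested. Without both 4 h replicates 12 and 13, which held 90.7 and 76.4 CPM of Ptgs2 against 3690 in replicate 11, the slope was 0.812, so a lower response of these 2 follicles stays open as part of the pattern. A difference between the cultures or library sets of the batches was not tested and stays open, and no biological explanation was tested.

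Star ranged from 16.4 to 1400 CPM among the 8 h follicles and from 37.7 to 890 among those of batch 1 at 1 h. Across 8 relations tested within sets of follicles of a time, Star went with the mean of 13 theca and stroma markers in batch 1 at 1 h (r = 0.92, permutation p = 2.4e-04, adjusted p = 0.00192, rho 0.85, adjusted p = 0.0229, and r = 0.86 without the 2 follicles farthest out) and at 8 h (r = 0.84, permutation p = 0.0011, adjusted p = 0.0044, rho 0.73, adjusted p = 0.0588, and r = 0.72 without 2). The relation missed the threshold at 0 h (r = 0.41, exact p = 0.273, adjusted p = 0.364, rho 0.43, and r = 0.89 without 2) and in batch 1 at 4 h (r = 0.64, permutation p = 0.0473, adjusted p = 0.126, rho 0.67, and r = 0.61 without 2), so with 2 of 4 sets theca and stroma cells kept with some follicles could account for the spread but stay undecided. Library depth was related to Star in 0 of 4 sets at an adjusted p under 0.05 (r of -0.05, -0.09, -0.42 and 0.42 at 0 h, 1 h, 4 h and 8 h, rho of -0.05, 0.05, -0.67 and 0.55, and r of 0.14, -0.09, -0.87 and 0.16 without 2, with adjusted p = 0.0775 for rho at 4 h by permutation), which excludes nothing at 9 to 11 follicles, although the bound set beforehand would have taken it as an exclusion. A higher share of theca cells as the source of the rise of Star is argued against, because the median change of 14 markers from 0 h to 4 h was -0.68 (SD 1.30) while Star rose by 7.41.

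In 100 splits of the samples per result, the real one included, 1 gave as many calls as the real one in each case, the real one itself. Shuffling put the real differences between groups into the spread, which lowers the calls of the other splits. The splits are therefore a low bar and do not exclude chance or differences between batches or animals. At 1 h against 0 h the real split called 2985 genes and the highest other 409, at 4 h against 0 h 4673 and 222, and at 8 h against 0 h 3892 and 0. From 1 h to 4 h the counts were 4733 and 1675, in a split whose first group of 13 held 10 of its own time, and from 4 h to 8 h 3567 and 620, in a split near the mirror of the real one. Over time they were 6883 and 14, and for the difference between batches 296 and 2. For the list tests the real grouping gave 45 calls and the highest other 40, with a median of 23, so camera with the preset correlation called many lists under arbitrary groupings, and the lists rest on their member counts and on the 12 calls with an estimated correlation, of which 9 held without the set-apart genes.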

How the results depend on the processing

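Thinning, restricting genes to those counted in batch 2, leaving out 0 h replicates 1 and 3, 4 h replicate 10 and 8 h replicate 4, and leaving out batch 2 libraries in the joint, batch difference and list tests were chosen after the result was seen. Of 6531 values of 302 named genes by comparison, 6311 kept their direction and side of the threshold, 191 lost the call, 19 gained one and 10 reversed, and 186 of the 302 kept both under every alternative run. RLE factors, no filter, no batch term, DESeq2, log2 TPM and the libraries without "_ds" left each count of called genes they gave within 1.5 times the count reported. The genes called overlapped less. At 1 h against 0 h RLE factors shared 2919 of the 2985 calls, DESeq2 2940, log2(TPM + 1) 2130 and the libraries without "_ds" 1855. At 8 h against 0 h log2(TPM + 1) shared 2715 of 3892. With a block for the replicate number the comparisons with 0 h called 355, 1479 and 852 genes at 1 h, 4 h and 8 h. Numbers 11 to 13 occur in batch 2 alone at 1 h and 4 h, so the block removes part of the comparison within that batch, and the numbers pair no follicles (median r of 62 same-number pairs -0.005, with 7 of 46 libraries closest to one of their own number). Batch 2 alone called 1828 genes at 1 h against 0 h and 701 from 1 h to 4 h, with 3 follicles per later time. A term for the library sets gave 2054 genes from 1 h to 4 h and 1446 from 4 h to 8 h, since plate 2 held 4 h alone. Thinned to 241442 counts, 3151 genes were tested, and 855, 1660 and 1389 were called against 0 h, 1898 and 1396 in the steps, 2576 over time and 84 between batches (33 higher and 51 lower in batch 2), which shows how far depth limits the counts. Of the 46 libraries 10 were left out in turn (0 h replicates 1 and 3, 1 h replicates 11 to 13, 4 h replicates 10 to 13 and 8 h replicate 4). In these runs the counts ranged from 2364 (without 1 h replicate 11) to 3025 at 1 h against 0 h, 4314 to 4803 at 4 h, 3593 to 4085 at 8 h, 4636 to 4859 from 1 h to 4 h, 3517 to 3741 from 4 h to 8 h and 6724 to 7100 over time. Rises made up 35.5% to 44.2% of the calls at 1 h against 0 h, 39.8% to 47.4% at 4 h, 38.2% to 48.9% at 8 h, 46.8% to 50.1% from 1 h to 4 h and 47.1% to 51.3% from 4 h to 8 h. Differences between batches ranged from 208 (without 4 h replicate 12) to 390 (without 1 h replicate 11), and list calls from 37 (without 0 h replicate 3) to 47.

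Of the 45 list calls 12 held with an estimated correlation, 33 with the library set term, 40 without the batch term, 30 of 44 thinned and 43 for genes counted in batch 2. Leaving out 0 h replicate 1 or 3, 8 h replicate 4, 1 h replicates 11 to 13, or 4 h replicates 11 or 13 ended 2 to 8 list calls, the luteinization list at 1 h among them in all but the last. Of the 12, EGF ligands with ERK feedback at 1 h (adjusted p = 0.0544) and cumulus expansion at 4 h (0.0906) and from 1 h to 4 h (0.0585) were not called in the fit without the set-apart genes. The library set term turned inflammation (adjusted p = 0.730) and mitochondrially encoded genes (adjusted p = 0.322) from 1 h to 4 h. The same term reversed Star from 1 h to 4 h (-0.42), Areg (0.97), Ereg (0.47), Star (0.50) and Sult1e1 (6.31) from 4 h to 8 h and mt-Nd3 from 1 h to 4 h (0.27), while batch 2 alone reversed Star (-0.43) and mt-Nd3 (0.30) from 1 h to 4 h. From 4 h to 8 h the library set term ended 19 calls given in the report. At 1 h it ended those of Nppc (-0.83), Fshr (-1.12), Mcm6 (-1.20), Cdh5 (1.09) and mt-Nd2 (0.20), at 4 h of Cyp11a1 (1.25) and Fos (-0.98), at 8 h of Krt18 (3.396), Serpinb2 (7.57), Snap25 (4.63) and Cxcl5 (2.71), and from 1 h to 4 h of Areg (0.19), Ereg (1.89), Pgr (2.56), Mvk (-1.92), Cyp17a1 (-3.01), Tle6 (-2.21), Lyz2 (-0.35) and Cdh5 (-0.11). Pgr at 1 h (4.04) and 8 h (4.603) and Egr1 at 8 h (1.43) gained one with it. The replicate block reversed Foxl2 at 1 h (0.58) and Tagln at 4 h against 0 h (-0.29), and none of these 10 values was called. Single libraries ended the calls of Has2 (1.38 without 1 h replicate 11, 1.92 without 12), Nppc (-1.22 without 1 h replicate 11), Egfr (-0.75, -0.88 and -0.80 without 1 h replicates 12 and 13 and 4 h replicate 11) and Cdh5 (1.46 without 4 h replicate 12) at 1 h against 0 h. They also ended those of Fos (-1.02 without 1 h replicate 12) and Cyp11a1 (1.42 without 1 h replicate 13) at 4 h, Krt18 at 8 h (2.12 and 2.19 without 1 h replicate 12 and 4 h replicate 13), Tle6 from 1 h to 4 h (-0.88 and -1.04 without 1 h replicate 12 and 4 h replicate 11) and Foxo1 from 4 h to 8 h (-0.55 to -0.59 without 5 libraries in turn), while Egr1 at 8 h gained one (1.11 without 0 h replicate 1 and 1.20 without 8 h replicate 4), as did Nr4a1 from 4 h to 8 h (-2.14 without 8 h replicate 4). Without 8 h replicate 4 the lists of immediate early genes, the progesterone receptor network and cholesterol synthesis were not called at 8 h, nor was the progesterone receptor network at 4 h (adjusted p between 0.05 and 0.1). Without the "_ds" libraries Has2 (1.32), Nppc (-0.97), Egfr (-0.89) and mt-Nd2 (0.61) at 1 h, Cyp11a1 (1.99) and Fos (-1.23) at 4 h and Foxo1 from 4 h to 8 h (-0.62) were no longer called. With limma on log2(TPM + 1) Ptgs2 (1.14), Has2 (0.90), Nppc (-1.31) and Fdxr (-0.79) at 1 h, Fos at 4 h (-0.46), Nppc (-0.92), Tle6 (-0.46) and Cdh5 (-0.85) from 1 h to 4 h, and Tnfaip6 (-1.28), Adamts1 (0.90), Foxo1 (-0.35) and Sult1e1 (-1.79) from 4 h to 8 h lost the call, while Egr1 at 8 h (1.32) and Nr4a1 from 4 h to 8 h (-1.65) gained one. On log2(TPM + 0.1) Fshr at 1 h (-1.14) was lost as well, and Ptgs2 and Has2 at 1 h kept the call. No filter ended the calls of Cdh5 at 1 h (1.86), Fos at 4 h (-1.09), Tle6 (-0.97) and Lyz2 (-1.61) from 1 h to 4 h and Foxo1 from 4 h to 8 h (-0.65), and DESeq2 that of Lyz2 from 1 h to 4 h (-1.55). DESeq2 added calls of Pgr (3.45), Ptx3 (3.85) and Sult1e1 (3.35) at 1 h and of Pgr at 8 h (3.27), batch 2 alone those of Pgr (4.21) and Sult1e1 (4.30) at 1 h, and no batch term those of Egr1 (1.04) and Cyp11a1 (1.37) at 8 h. Batch 1 alone did not call Adamts1 (1.03) or Foxo1 (-0.50) from 4 h to 8 h, and the replicate block gave Foxo1 at -0.62, not called. Thinning ended the calls of Areg (3.62), Ptgs2 (4.25), Tnfaip6 (2.76), Runx1 (0.25), Has2 (1.57) and Nppc (-1.17) at 1 h, of Areg at 8 h against 0 h (3.73) and of Fos (-1.15), Fshr (-0.88) and Foxo1 (-0.66) from 4 h to 8 h. Where no reason is given here, the cause was not tested.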

Other observations

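All families in this part were chosen after their values were seen, from 28 tried, of which 26 had at least 3 genes measured. Ribosome biogenesis genes, which process ribosomal RNA and assemble ribosomal subunits, rose and came down again. Of 46 measured, 36 rose and 3 fell at 4 h against 0 h (camera adjusted p = 1.4e-12, and adjusted p = 9.8e-04 with an estimated correlation; median 1.22), and 41 rose and 1 fell from 1 h to 4 h (7.9e-16 and 1.6e-04; median 1.42). From 4 h to 8 h 0 rose and 34 fell (1.7e-15 and 6.6e-04; median -0.85). These medians kept their sign under every scaling tried. No family was tested with a term for the library sets. All 4 h follicles of batch 1 came from a plate that held no other time. A change of a family from 4 h to 8 h is therefore also a difference between plates. Nop56, a core protein of the particles that modify ribosomal RNA, changed by 3.07 ± 0.19 at 4 h against 0 h and by -2.13 ± 0.15 from 4 h to 8 h. Transfer RNA synthetases, which charge transfer RNAs with amino acids, moved alike, as 14 of 17 rose at 4 h against 0 h (camera adjusted p = 1.2e-07, and adjusted p = 0.0206 with an estimated correlation), 14 rose from 1 h to 4 h (3.7e-07 and 0.0271), and 1 rose and 9 fell from 4 h to 8 h (0.00132 and 0.187). Nars, the synthetase for asparagine, rose by 3.07 ± 0.19 at 4 h and changed by -1.72 ± 0.15 from 4 h to 8 h.

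Nuclear genes for respiratory complex I were lower after hCG. Of 36 measured 0 rose and 34 fell at 4 h against 0 h (median -1.33, camera adjusted p = 7.8e-12, and adjusted p = 0.0557 with an estimated correlation), among them Ndufv3 (-2.34 ± 0.32). At 1 h 21 fell (6.4e-05 and 0.419) and at 8 h 28 (2.2e-07 and 0.273), with 0 rising. From 1 h to 4 h 0 rose and 31 fell (1.1e-07 and 0.172), while from 4 h to 8 h 13 rose and 2 fell (0.0130 and 0.709, median 0.29). With log2(TPM + 1) the median at 4 h was -0.74 and 25 fell, and at 8 h 4 rose and 13 fell. Tubulins, the subunits of microtubules, were higher, with 12 of 14 rising at 4 h against 0 h (camera adjusted p = 3.1e-07, and adjusted p = 0.182 with an estimated correlation) and 13 at 8 h (2.8e-09 and 0.273), including Tubb6 (4.22 ± 0.38 at 8 h). Zp3, which encodes a protein of the coat around the oocyte, had mean CPM of 2.30, 3.90, 2.57 and 3.85 at 0 h, 1 h, 4 h and 8 h.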
